A study of Homo sapiens with 8 samples.

How the data were processed

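RNA was taken from human intestinal myofibroblasts of strictured colon in Crohn's disease at passages 8 to 10, after exposure to scramble siRNA or CDH11 siRNA for 8 hours and a further 48 hours, with 4 libraries in each of 2 groups. Per the labels' protocols, total RNA was purified on columns and libraries were made with Illumina TruSeq kits. Groups were taken from the treatment label of each sample. The titles call the scramble libraries untreated, and the design text speaks of triplicates where the labels give 4 libraries per group; the labels were followed.

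Per the submitters' processing notes, the tools were Trim Galore 0.4.4, FastQC 0.11.7, HISAT2 2.1.0, SAMtools, featureCounts 1.5.2 of the Subread package, R 3.6.2 and DESeq2, with the genome build GRCh38.p13. The annotation release, the strand setting, the treatment of reads with several alignments, and the siRNA sequences are not given in the sources used here. Without the strand setting, reads of overlapping genes on opposite strands cannot be told apart. Of the 114 genes named by rule, 37 overlap another tested gene in GENCODE 29.

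The deposited counts are whole-number read counts per gene for 60676 gene identifiers, made by the authors and not normalised. A second deposited table, whose name refers to log2 CPM, holds 21069 genes. Its values proved to be a linear signal, the authors' counts divided by 1 size factor per library, and were neither logarithms nor CPM. The genes in it had a count total of at least 11 over the 8 libraries, and those left out of it at most 10. It was used in 1 alternative only, as log2 of the value plus a pseudocount of 1. No row of the count table lacked a gene.

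Gene symbols came from a table of gene names for 42009 identifiers and from GENCODE 29 for another 16566, and 2101 stayed without a name. Coordinates are those of GENCODE 29 on GRCh38. The count total per library was 26607835 to 36731480, 251717226 in all. The most abundant gene, IGFBP5, took 4.07% to 4.26% of the scramble counts and 2.50% to 2.71% of the knockdown counts, and the 20 most abundant took 14.0% to 14.2% and 11.7% to 11.9%. All 37 mitochondrial genes had 0 reads in each library. Sequencing reads without molecular identifiers are not independent molecules, so floors cover counting error only.

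The main test was edgeR 4.0.16 (R 4.3.3) on the counts, with TMM factors, filterByExpr by group with default settings (a minimum count of 10 and a minimum total of 15), and glmQLFit and glmQLFTest with default settings and no covariate. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of its F statistic. CPM values are scaled by the TMM factors, and the common biological coefficient of variation was 8.42%. Replicate pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.72 to 13.3, so no library was treated as a repeat of another.

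Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 28 lists with at least 3 tested members. There were 32 lists, 23 of pathways or complexes and 9 of cell type markers. Changed members were also counted with p-values adjusted over the list alone. Camera with an estimated correlation and fry were alternatives.

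The lists, the main tests, the alternatives and the rule for named genes were set before the data were examined, and tests added later are named as such where they are given. The rule named CDH11, the 12 largest rises and the 12 largest falls among changed genes with a mean log2 CPM of at least 1 and no overlap between the groups, without clone names and pseudogenes, and up to 2 rises and 2 falls per list. Other members of a list are given to describe it and were chosen after their values were seen. Some genes are not reported. Genes that could reveal the sex of a donor were left out of the text and of the tables.

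The alternatives were other scalings (RLE, upper quartile, library size alone), no filter on low counts, a filter at a CPM of 1 in 4 libraries, DESeq2 1.42.0, limma-voom, robust edgeR, limma-trend on the second table, the replicate number as a block, glmTreat against a fold of 1.2, and leaving out each library in turn. The test was tried on simulated counts for the 15497 genes of this comparison, with 200 genes changed. It recovered 36% of those changed 1.25-fold, 80% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, and 14 of its 167 calls (8.38%) were false. The 200 are far fewer than the 7794 genes called in the data, so these rates need not hold for the real comparison. Of simulated lists, 0 were called when none was shifted, and 2 when the collagens alone were, the collagens being 1 of them. The simulated genes were drawn independently of each other, so these runs do not show how often camera calls lists of correlated genes.

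To look for off-target silencing, log2 fold changes of 12688 genes with an annotated 3' UTR of at least 50 bases were regressed on the presence of each 7-base word, with UTR length, base composition and mean expression as covariates, and compared with 200 permutations of the genes. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used.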

Results

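RNA sequencing measured gene expression in human intestinal myofibroblasts, the contractile, matrix-producing cells of the gut wall, cultured from strictured colon in Crohn's disease, an inflammatory bowel disease. The cells, at passages 8 to 10, were given a small interfering RNA (siRNA) against CDH11, which encodes the cell-cell adhesion protein cadherin-11, or a scramble siRNA with no intended target. Exposure lasted 8 hours, and a wait of 48 hours followed. There were 4 libraries per group and 8 in all. Each library held 26607835 to 36731480 counted reads, and 15497 genes had enough reads to be tested. The labels do not say whether the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

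The comparison asks which transcripts differ after knockdown of CDH11. The target itself was measured first. CDH11 (ENSG00000140937) lies on the minus strand of chromosome 16, from 64943753 to 65126112 in GRCh38 with GENCODE 29. It fell from 535 ± 10.0 CPM (counts scaled to library size; mean ± SD, n = 4) with scramble siRNA to 15.9 ± 0.958 (n = 4) with CDH11 siRNA, 33.8-fold lower. The 4 knockdown libraries held 469, 511, 472 and 463 CDH11 reads, and the 4 scramble libraries 19471, 16424, 15073 and 18648. The remaining level was 2.96% of the scramble mean. The log2 fold change was -5.08 with a standard error of 0.0455, and the adjusted p of edgeR's quasi-likelihood test was 3.15e-16. An exact two-sided permutation test on log2 CPM (n = 4 and 4) gave p = 0.0286, the smallest value this design allows.

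**Figure D1:**
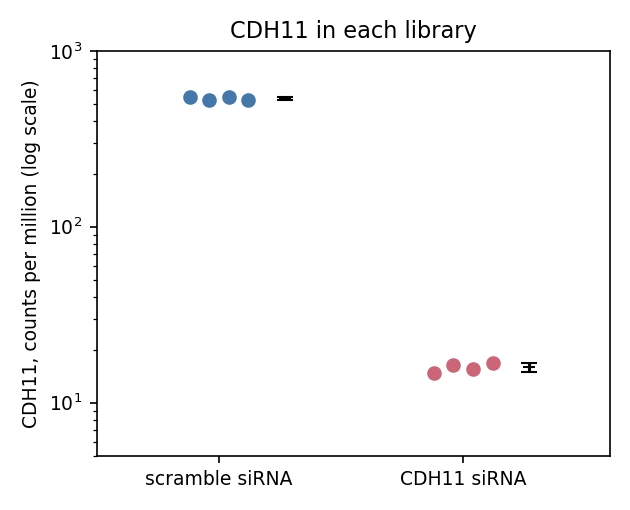
CDH11 in CPM on a log axis, 1 point per library, for scramble siRNA (n = 4) and CDH11 siRNA (n = 4); the black bar gives the mean and SD of each group. The knockdown libraries lie between 14.7 and 16.9, below the scramble libraries at 525 to 544.

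In the knockdown libraries 31 of 34 tested interferon response genes and 25 of 37 cytokine and NF-kB target genes rose, while 31 of 36 matrix glycoprotein genes, 16 of 24 collagens and 20 of 23 contractile genes fell. All 5 lists passed in camera with a preset correlation, and none with an estimated correlation (adjusted p = 0.183, and 0.342 for the collagens). IL24, a cytokine of the IL-10 family, was 50.8-fold higher, going from 3.37 ± 0.349 to 172 ± 17.0 CPM (SD, n = 4 each). MMP1, the interstitial collagenase, was 16.2-fold higher, from 131 ± 5.31 to 2115 ± 156 CPM. CXCL12, a chemokine made by stromal cells, was 10.7-fold lower, from 634 ± 25.2 to 59.1 ± 2.29 CPM. COL1A1, which encodes a chain of type I collagen, was 2.43-fold lower, from 6977 ± 437 to 2869 ± 300 CPM.

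Of the 15497 genes tested, 7794 (50.3%) differed between the groups at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Of these, 3878 were higher and 3916 lower in the knockdown libraries. With library size alone as the scaling, the split was 4927 higher and 3240 lower. A difference of at least 2-fold was seen for 1238 genes, 599 higher and 639 lower. In 7149 of the 15497 tested genes all 4 libraries of one group lay above all 4 of the other, which chance gives for 2.86% of genes, and 6834 of these were called changed. The first principal component of log2 CPM, which separated the groups, held 63.1% of the variance. The second, with 8.80%, set knockdown replicate 3 (29.8) apart from knockdown replicate 4 (-22.7).

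Of the 12 genes with the largest rises among named-symbol genes with a mean log2 CPM of at least 1 over the 8 libraries and no overlap between the groups, IL24, CSF2, CCL20, IL1B, IL33 and IL11 encode cytokines or chemokines, PTGS2 makes prostaglandins and MMP1 cleaves collagen. CSF2, the growth factor GM-CSF, was 29.01-fold higher (log2 fold change 4.86, standard error 0.188). The chemokine gene CCL20 was 14.7-fold higher, IL1B, which encodes interleukin-1 beta, 11.9-fold, PTGS2, the inducible cyclooxygenase, 11.8-fold, and IL33, an epithelial and stromal alarmin, 10.4-fold. IL11, a cytokine of the IL-6 family, was 7.35-fold higher. The others were the transcription factor gene FOSB (21.9-fold), the protease inhibitor SERPINB2 (14.3-fold), the amino acid transporter SLC6A15 (12.1-fold) and the long noncoding RNA LUCAT1 (8.95-fold). FOSB varied within the knockdown group, at 17.5 ± 15.1 CPM (SD, n = 4), and its log2 fold change went from 4.45 to 3.67 without knockdown replicate 3. LUCAT1 is annotated as antisense to ADGRV1 and FOSB lies opposite ERCC1, and the strand setting of the counting is not given in the sources used here.

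By the same rule, the largest fall after CDH11 itself was that of the metalloproteinase gene ADAMTS15, 22.5-fold lower (log2 fold change -4.49, standard error 0.215). Its chromosome 11 neighbour ADAMTS8 was 14.8-fold lower. SST, the hormone somatostatin, was 16.3-fold lower, PDZRN4 15.7-fold, the alcohol dehydrogenase ADH1B 14.1-fold and the kinase gene DCLK1 14.1-fold. SULF2, which trims sulfate from heparan sulfate, fell 12.7-fold, from 392 ± 9.61 to 30.9 ± 3.10 CPM (SD, n = 4 each). The growth factor IGF1 was 10.8-fold lower, the hyaluronan synthase HAS3 10.7-fold and the chemokine CXCL14 9.77-fold. For these 23 genes the edgeR adjusted p was at most 1.63e-05, the value of FOSB.

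**Figure D2:**
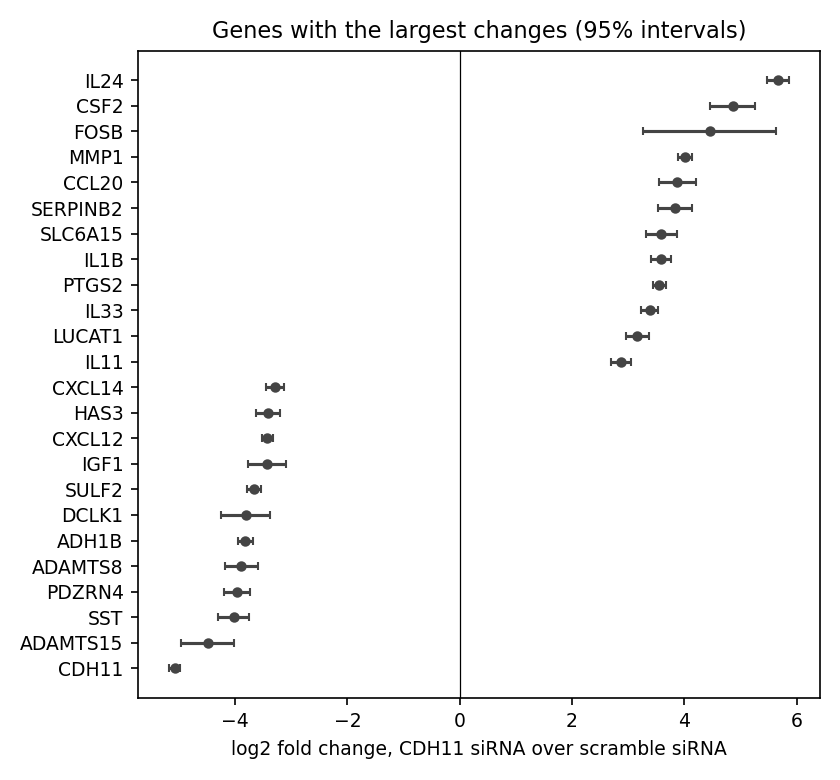
Fitted log2 fold change of CDH11 siRNA over scramble siRNA (n = 4 each) for the 12 largest rises and 12 largest falls among named-symbol genes with a mean log2 CPM of at least 1 over the 8 libraries and no overlap between the groups, with 95% intervals. The rises run from 2.88 (IL11) to 5.67 (IL24) and the falls from -3.29 (CXCL14) to -5.08 (CDH11).

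The interferon response list held the most uniform rise. Of its 34 tested members 31 rose, 2 fell and 1, IFI27, did not pass, with the same counts when adjusted over the list alone, and the median log2 fold change was 1.58. The antiviral enzyme gene RSAD2 rose 4.95-fold, from 44.5 ± 4.37 to 221 ± 16.2 CPM (SD, n = 4 each), and IFI44L 4.36-fold. The RNA sensors RIGI (log2 fold change 1.55) and IFIH1 (from 51.2 to 145 CPM) also rose, as did the chemokines CXCL10 (1.28) and CXCL11 (1.98). The transcription factor IRF1 (-0.43) and the double-stranded RNA receptor TLR3 (-0.12) fell. The edgeR adjusted p of TLR3 was 0.0212, but 0.0534 without scramble replicate 1, 0.0786 without scramble replicate 4, 0.0579 without knockdown replicate 1, 0.0555 without knockdown replicate 4, 0.222 with library size alone and 0.0872 with no filter on low counts. The camera test gave the list an adjusted p of 1.88e-17, and an adjusted p = 0.183 with an estimated correlation.

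Cytokine and NF-kB target genes moved both ways, with more rises. Of 37 tested, 25 rose and 7 fell, also when adjusted over the list alone, with a median log2 fold change of 0.59. CXCL8 (log2 fold change 2.65), IL6 (1.43), LIF (2.78) and CSF3 (3.92) rose, while CXCL12 (-3.42), CCL8 (-2.75), CCL11 (-1.36) and the adhesion receptor VCAM1 (-1.13) fell. The camera adjusted p was 4.57e-06, and the adjusted p = 0.183 with an estimated correlation. On the list of inflammation-associated fibroblast genes 17 of 21 rose and 4 fell, also when adjusted over the list alone, with a median of 2.37. The falls were WNT2 (-2.13), PDPN (-0.76), the oncostatin M receptor OSMR (-0.70) and CXCL6 (-0.52). Camera gave this list an adjusted p of 3.73e-07, and an adjusted p = 0.183 with an estimated correlation. It shares IL24, PTGS2, CXCL5, CXCL6, CXCL8 and CSF3 with the cytokine list, so these are not separate results. MMP1, MMP3 and MMP10 are also on the list of matrix proteases.

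Immediate early genes, which are induced within minutes of a stimulus, rose in 17 of 22 cases and fell in 1, FOSL2 (log2 fold change -0.78), also when adjusted over the list alone. The median was 1.12, and EGR3 (2.94), EGR2 (2.24) and FOSL1 (1.67) were among the rises. EGR3 varied within the knockdown group, at 4.51 ± 4.18 CPM (SD, n = 4), and its log2 fold change was 2.06 without knockdown replicate 3. The mean log2 CPM of the list lay between 3.37 and 3.72 in the scramble libraries and was 4.52, 4.98, 5.35 and 4.30 in knockdown replicates 1 to 4. In camera the adjusted p was 1.25e-04, and the adjusted p = 0.431 with an estimated correlation.

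Of 36 tested matrix glycoprotein and proteoglycan genes 31 fell and 4 rose, also when adjusted over the list alone, with a median log2 fold change of -0.84. Matrilin-2, MATN2, fell 5.23-fold, the microfibril gene MFAP4 4.01-fold, and decorin, DCN, by 1.24 on the log2 scale. The rises were HAS2 (4.57-fold), which makes hyaluronan, the basement membrane gene NID2 (2.34-fold), and THBS1 (log2 fold change 0.16) and THBS2 (0.14). The camera adjusted p was 1.79e-11, and the adjusted p = 0.183 with an estimated correlation. Reads of MATN2 are uncertain because the abundant RPL30 overlaps it on the other strand.

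Among 24 tested collagen genes 16 fell and 5 rose, also when adjusted over the list alone, with a median log2 fold change of -0.63. COL14A1 fell 7.65-fold, from 939 ± 15.8 to 123 ± 13.1 CPM (SD, n = 4 each), and COL18A1 3.27-fold. COL3A1 (log2 fold change -0.78), COL5A1 (-1.14) and COL6A3 (-0.90) fell too. The rises were COL7A1 (3.80-fold), the anchoring fibril collagen, COL10A1 (2.30-fold), COL13A1 (0.51), COL8A1 (0.19) and COL4A1 (0.10), the last 3 as log2 fold changes. COL10A1 lies inside NT5DC1 on the other strand, which held 19.2 times its reads. Camera gave the collagens an adjusted p of 6.04e-04, and an adjusted p = 0.342 with an estimated correlation.

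Of 22 genes for collagen processing and crosslinking 13 fell and 2 rose, LOX (1.24-fold) and PLOD2 (1.08-fold), also when adjusted over the list alone. The procollagen N-proteinase ADAMTS14 (3.09-fold) and PCOLCE (2.71-fold), which enhances the procollagen C-proteinases, were among the falls. The median log2 fold change was -0.27, the camera adjusted p 0.00104, and the adjusted p = 0.427 with an estimated correlation. Matrix proteases and their inhibitors divided instead. Of 32 tested 14 rose and 15 fell, or 14 and 16 when adjusted over the list alone. MMP3 (6.96-fold), MMP10 (log2 fold change 2.72), TIMP1 (1.12) and the tissue plasminogen activator PLAT (1.67) rose, while ADAMTS5 (-1.11), TIMP2 (-0.77) and MMP14 (-0.55) fell. The median was -0.08 while the mean was 0.40 and camera pointed upward, at an adjusted p of 0.804.

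Contractile genes of the myofibroblast fell in 20 of 23 cases and rose in 1, SMTN (1.31-fold), also when adjusted over the list alone. ACTA2, the smooth muscle actin that marks myofibroblasts, fell 2.62-fold, from 192 ± 7.66 to 73.5 ± 9.04 CPM (SD, n = 4 each). LMOD1 fell 3.36-fold, and TAGLN by 1.35, MYLK by 0.75 and CALD1 by 0.65 on the log2 scale. ACTG2, at a log2 fold change of -0.06, did not pass. The median was -0.39, the camera adjusted p 2.96e-07, and the adjusted p = 0.183 with an estimated correlation. Of 8 mature smooth muscle markers, SMTN rose and 5 fell, LMOD1, CNN1, SYNPO2, NPNT and MYOCD, the coactivator of smooth muscle genes (3.90-fold), also when adjusted over the list alone. Their camera adjusted p was 0.0141, and the adjusted p = 0.183 with an estimated correlation. SMTN, LMOD1, CNN1 and SYNPO2 are on the contractile list as well, so the results of these lists overlap.

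Markers of the fibroblast lineage were lower as well. On the fibroblast list 12 of 13 fell, among them THY1 (2.53-fold), PDGFRB (2.24-fold) and PDGFRA (log2 fold change -0.37), and FAP rose 1.18-fold, with a camera adjusted p of 3.45e-07 and an adjusted p = 0.183 with an estimated correlation. Of 8 tested pericyte markers 6 fell and none rose, including CSPG4 (2.38-fold) and NOTCH3 (log2 fold change -0.71), with a camera adjusted p of 0.00166 and an adjusted p = 0.183 with an estimated correlation. These counts did not differ when adjusted over the list alone. The fibroblast list shares COL1A1, COL1A2, COL3A1, COL6A3, DCN and LUM with the matrix lists, and PDGFRB with the pericyte list.

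Among 15 tested cadherins and catenins, in which CDH11 was not counted, 8 fell and 1 rose, also when adjusted over the list alone. The protocadherin PCDH7 fell 2.53-fold and CDH6 1.64-fold, and CDH2, N-cadherin, fell by 0.29 on the log2 scale, while CDH13 rose 1.12-fold. Beta-catenin, CTNNB1, had a log2 fold change of 0.06 and did not pass. The list's adjusted p in camera was 0.0371, 0.0673 without knockdown replicate 3 and 0.0593 with library size alone, and the adjusted p = 0.192 with an estimated correlation.

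Of 28 tested hypoxia and glycolysis genes 18 rose and none fell, or 18 and 1 when adjusted over the list alone, with a median log2 fold change of 0.21. The hexokinase HK2 rose 1.98-fold, from 223 ± 2.35 to 442 ± 8.81 CPM (SD, n = 4 each), CA9 3.36-fold and VEGFA by 0.73 on the log2 scale, while GAPDH (-0.03) and ENO1 (0.02) did not pass. The camera adjusted p was 6.07e-06, and the adjusted p = 0.275 with an estimated correlation. Of 23 cholesterol synthesis genes 14 rose and 3 fell, or 15 and 3 when adjusted over the list alone. STARD4 rose 1.62-fold and MSMO1 1.44-fold, and PMVK (log2 fold change -0.22) was among the falls. The median was 0.26, the camera adjusted p 0.00166, and the adjusted p = 0.275 with an estimated correlation. In edgeR the adjusted p of PMVK was 0.0204, and it was 0.0740 without scramble replicate 1, 0.0591 without knockdown replicate 1, 0.0553 without knockdown replicate 4 and 0.0590 with library size alone.

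Of 27 tested mitosis genes 11 fell and none rose, or 10 and none when adjusted over the list alone, with KIF20A 2.18-fold and CDC20 1.36-fold lower and a median log2 fold change of -0.16. For this list camera gave an adjusted p of 0.0362, and it was 0.116 without scramble replicate 2, 0.0819 without scramble replicate 3, 0.0673 without knockdown replicate 3 and 0.0593 with library size alone, with an adjusted p = 0.736 with an estimated correlation. Of 26 DNA replication genes 12 rose and 4 fell, or 13 and 4 when adjusted over the list alone. The origin licensing gene CDC6 was 1.65-fold higher, and the nucleotide synthesis genes TYMS and TK1 were 1.53-fold and 1.27-fold lower, and MCM6 fell by less (log2 fold change -0.24). The list did not pass in camera (adjusted p 0.0794), but did without scramble replicate 2 (0.0496) or 3 (0.0407), without knockdown replicate 4 (0.0411) and with no filter on low counts (0.0190).

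Other pathway lists held many changed genes in both directions and did not pass in camera. On the TGF-beta list 11 of 37 rose and 18 fell, or 11 and 19 when adjusted over the list alone. IL11 (7.35-fold) and CCN2 (2.14-fold) rose, as did INHBA, by 1.54 on the log2 scale. BMP4 (2.82-fold) and LDLRAD4 (2.27-fold) fell, and SMAD3 fell by 0.60 on the log2 scale. Of 27 Wnt genes 9 rose and 13 fell, or 9 and 14 when adjusted over the list alone. The Wnt inhibitors DKK1 (4.02-fold) and NOTUM (4.51-fold) rose, and the ligands WNT2 (4.37-fold) and WNT2B (3.85-fold) fell. NOTUM was low in both groups, at 0.241 ± 0.137 CPM with scramble siRNA and 1.06 ± 0.321 with CDH11 siRNA (SD, n = 4 each). Of 23 YAP and TAZ targets 8 rose, among them CCN2 (2.14-fold), and 10 fell, among them IGFBP3 (1.83-fold) and FOXF2 (1.71-fold), also when adjusted over the list alone. Of 30 integrin and focal adhesion genes 10 rose and 14 fell, or 11 and 14 when adjusted over the list alone, with ITGA2 2.59-fold higher and ITGA4 and ITGA8 both 2.75-fold lower. The camera adjusted p values of these 4 lists were 0.193, 0.444, 0.849 and 0.444. For the YAP and TAZ targets the median log2 fold change was 0.01 and the mean 0.08, against a downward camera direction, and the median was -0.01 with upper-quartile factors. The integrin median turned from -0.02 to 0.04 with library size alone.

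Of 27 p53 target and apoptosis genes 12 rose and 7 fell, or 14 and 8 when adjusted over the list alone, with GDF15 5.72-fold and PMAIP1 (log2 fold change 1.07) higher and TP53INP1 2.01-fold lower. Of 29 genes of the unfolded protein and integrated stress responses 11 rose and 12 fell, also when adjusted over the list alone. ATF3 (3.19-fold) and CHAC1 (2.08-fold) rose, while the serine synthesis genes PSAT1 (3.01-fold) and PHGDH (2.29-fold) fell. Growth factors and receptors included 16 rises and 13 falls among 34, also when adjusted over the list alone, with the EGF receptor ligands AREG (4.36-fold) and HBEGF (4.16-fold) higher and IGF2 2.78-fold lower. The RNA interference machinery had 4 rises, AGO2 (1.44-fold), XPO5 (1.30-fold), TNRC6A (log2 fold change 0.34) and TARBP2 (0.28), and 4 falls, AGO4, TNRC6C, AGO1 and DROSHA (-0.26, -0.32, -0.23 and -0.14), among 13, also when adjusted over the list alone. The camera adjusted p values of these 4 lists were 0.243, 0.849, 0.720 and 0.849. The stress response and RNA interference medians were -0.03 each, against means of 0.02 and 0.04 and an upward camera direction, and they turned to 0.03 and 0.04 with library size alone. For the growth factors the median was 0.02 and the mean -0.03.

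Most markers of other cell types had too few reads to be tested, and the tested ones moved both ways. Some were not low. In the scramble and knockdown groups TEK stood at 106 and 81.6 CPM, UCHL1 at 134 and 118, and KRT8 at 72.7 and 26.2. Of 14 epithelial markers 2 had enough reads to be tested, KRT8 (2.77-fold lower) and KRT18 (1.72-fold higher), which overlap each other on opposite strands. Of 14 immune markers only CD14, which fibroblasts can also express, was tested, and it fell 2.25-fold, from 58.2 ± 1.62 to 25.9 ± 2.49 CPM (SD, n = 4 each). Among the untested ones, PTPRC, the pan-leukocyte gene CD45, had 7 reads in the scramble group and 12 in the knockdown group, CSF1R 4 and 24, CD68 21 and 46, and FCER1G 14 and 26. Of 12 endothelial markers 5 were tested. PECAM1 rose from 0.0875 ± 0.101 to 0.638 ± 0.147 CPM (SD, n = 4 each; log2 fold change 2.86, but 3.49 without scramble replicate 4 and 3.599 with limma-voom) and EGFL7 rose 1.38-fold, FLT1 (3.22-fold) and TEK (1.29-fold) fell, and VWF did not pass. The endothelial median log2 fold change was -0.33 and the mean 0.19. Of 4 tested enteric glia and neuron markers the receptor gene RET rose (1.61-fold), and TUBB3 (1.57-fold) and UCHL1 (1.14-fold) fell. Of 3 tested mesothelial markers KRT18 rose, and KRT8 and BNC1 (1.16-fold) fell. Several of these calls were weak. In edgeR the adjusted p of RET was 0.0501 without scramble replicate 1 and 0.0548 without knockdown replicate 3. That of UCHL1 was 0.0561 without scramble replicate 1, 0.0653 without scramble replicate 3 and 0.0753 with library size alone. For TUBB3 it was 0.0608, 0.0620, 0.0895 and 0.0640 without scramble replicates 1, 2, 3 and 4, 0.0731 and 0.0573 without knockdown replicates 2 and 3, and 0.0568 with library size alone. For BNC1 it was 0.0676, 0.154, 0.0617 and 0.0580 without scramble replicates 1, 2, 3 and 4, 0.126, 0.0623 and 0.0585 without knockdown replicates 1, 3 and 4, 0.132 with library size alone and 0.0535 in DESeq2. In camera the adjusted p values of the endothelial, enteric and mesothelial lists were 0.721, 0.842 and 0.548. Of the adipocyte markers 2 were tested, LEP (2.66-fold higher) and PPARG (1.41-fold lower). The counts of these marker lists were the same when adjusted over the list alone. All 37 genes of the mitochondrial genome had 0 reads in every library, so the mitochondrial list was not tested.

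**Figure D3:**
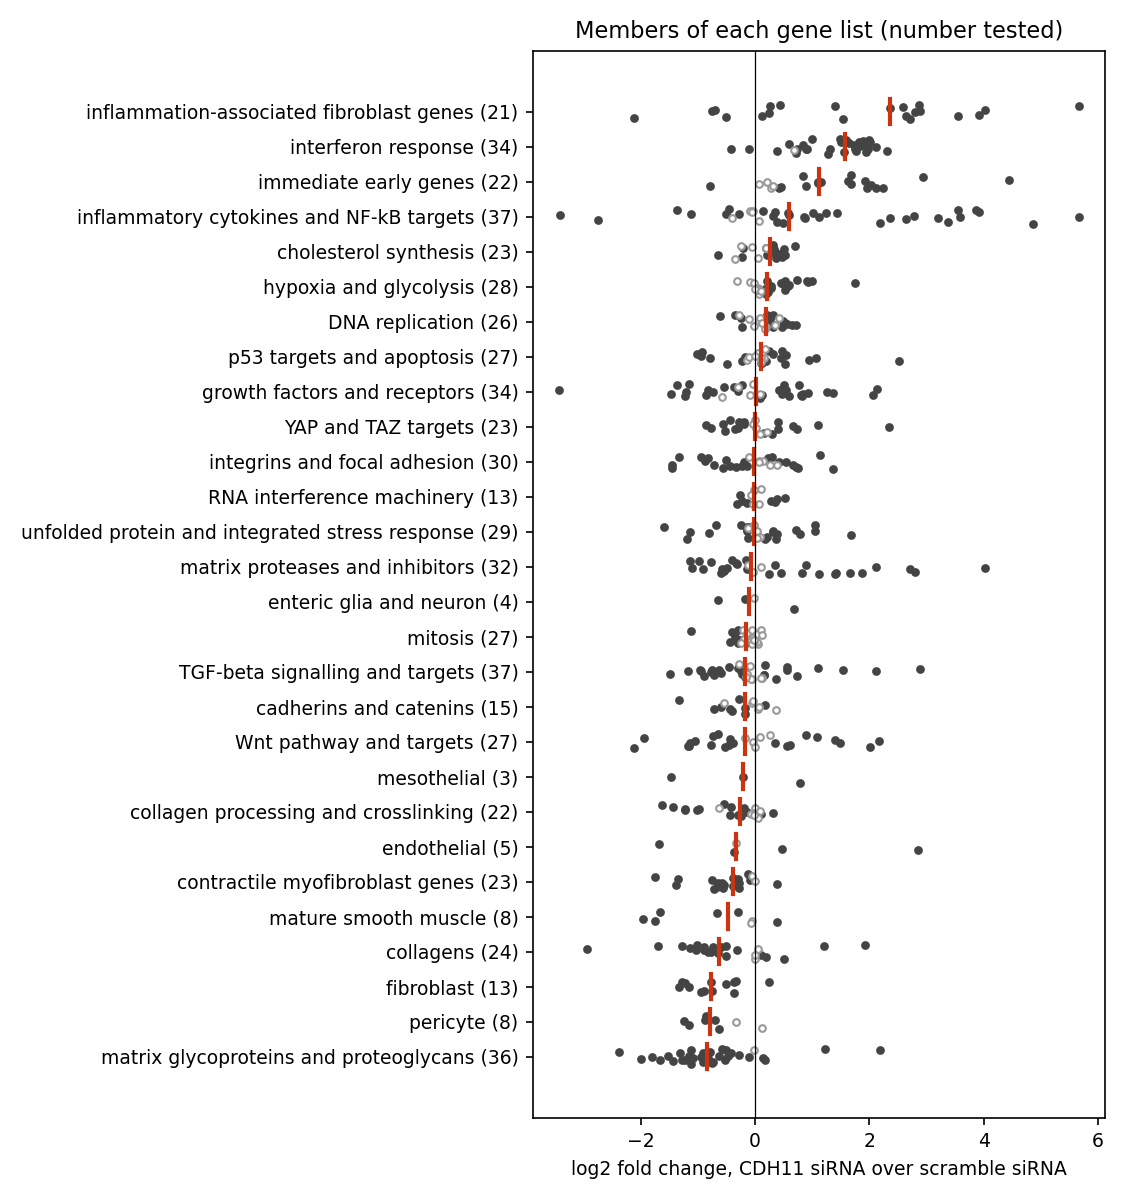
Log2 fold change of CDH11 siRNA over scramble siRNA (n = 4 each) for the tested members of 28 gene lists, 1 point per gene, filled where the edgeR adjusted p passed 0.05 and open where it did not; the red bar is the list's median. The medians run from -0.84 for matrix glycoproteins and proteoglycans to 2.37 for the inflammation-associated fibroblast genes.

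In all, 15 of the 28 tested lists passed in camera with a preset correlation between genes of 0.01, and 0 with a correlation estimated for each list, where the smallest adjusted p was 0.183. Fry, which asks whether a list's genes move one way on balance without setting them against other genes, passed 24.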

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

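The tests for leukocyte RNA, for the siRNA duplex, for loss of CDH11 and for genes unstable within a group were chosen after the results were seen. Those on the matrix genes and on other splits were chosen before.

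Among the named genes, 13 of 228 sets of 4 libraries held 1 library far from the other 3, where about 1 in 20 would by chance. In the knockdown group all 3 were replicate 3, with ATF3 at 37.7 CPM against 16.8 to 17.5 in the others, AGO2 at 70.2 against 82.8 to 84.0, and HK2 at 455 against 437 to 439. Scramble replicate 3 was highest for SULF2 (407 CPM), PCDH7 (73.2), CHAC1 (11.22) and TUBB3 (2.81). Scramble replicate 2 was highest for BNC1 (18.9 CPM) and lowest for IL11 (4.96) and LEP (0.224). Scramble replicate 1 was lowest for COL7A1 (143 CPM) and EGR3 (0.447), and scramble replicate 4 for KRT18 (2.40).

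IFNB1, the gene of interferon beta, was left out of the test for low counts. It had 21 reads over the 4 knockdown libraries, 3 to 10 in each, and 0 over the 4 scramble libraries. With reads pooled over each group and scaled to library size, it was 7.53-fold above a floor of 3 reads for the scramble group. This is not a strict lower bound, because the counting error of the 21 reads is left out. IFNL1 had 4 reads in the knockdown group and 0 in the scramble group, and IFNA1 and IFNG had 0 in both.

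In the knockdown libraries 31 of 34 interferon, 25 of 37 cytokine and 17 of 22 immediate early genes rose, and 2, 7 and 1 fell, with camera adjusted p = 0.183, 0.183 and 0.431 with an estimated correlation. Leukocyte RNA is argued against, because PTPRC, TYROBP and FCER1G together reached 0.324 CPM in the knockdown libraries while IL1B alone stood at 176 CPM. CD68 and CSF1R had more reads in the knockdown group but reached only 0.386 and 0.196 CPM. Sensing of the siRNA duplex by the cell and loss of CDH11 itself cannot be told apart, since both allow the 31 interferon genes that rose. By the treatment labels every control library received the scramble duplex, though the titles call these libraries untreated. Under the labels, sensing of any duplex alike would be shared by both groups, so only sensing particular to the CDH11 duplex stays open. The labels do not speak of more than 1 CDH11 siRNA, which keeps this and loss of CDH11 from being separated. Off-target silencing by the CDH11 siRNA was not tested for these genes and stays open too.

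Matrix genes were lower on balance in the knockdown libraries (for the 2 lists, camera adjusted p = 0.183 and 0.342 with an estimated correlation), with a median log2 fold change of -0.78 ± 0.0785 (bootstrap SD) over 60 genes. For the 55 of these outside the 20 most abundant genes, the median was -0.79. It was -0.79 ± 0.0874 after those 20 were left out. They took a small share of the counts and TMM scaling was already in use, so leaving them out could hardly move the median. Whether a few abundant genes gave the fall is therefore not decided by leaving them out. Other values argue against that cause for these 2 lists. The most abundant genes took a smaller share of the counts in every knockdown library than in any scramble library. Such a shift would raise the other genes in the knockdown libraries, not lower them. With library size alone, the medians were still -0.78 for the matrix glycoproteins and -0.57 for the collagens, against 0.07 for all genes. GC content or gene length is argued against as the whole cause, with a median of -0.71 ± 0.0761 after their trends were removed. Among 7-base words of the CDH11 transcript, GACATAT in a 3' UTR went with the lowest fold changes. It was in 6 of the 60, and the other 54 had a median of -0.78 ± 0.0911, so direct silencing through that word does not cover these 54. With 6 carriers the median could hardly have moved, and the siRNA sequence was not used here. Off-target silencing as such therefore stays open. An effect of losing CDH11, and an effect of the cytokines that rose, stay open and were not tested.

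Some genes varied several-fold between libraries of 1 group. Of 13285 genes with a mean above 30 normalised counts, 115 had a range above 4-fold within a group, such as TMEM14C with 582 in scramble replicate 2 and 5 to 13 in the other 7 libraries. They lie in runs, with 68.7% having another such gene within 1 Mb against at most 33.0% in 1000 random sets matched on mean count, as reads shared with a near-identical copy of a locus could give, though copies were not searched for and other regional causes stay open. Real variation of early-response transcripts also stays open. The 4 genes FOS, FOSB, EGR1 and EGR3 (3.48% of them) are on the immediate early list, whose 22 genes are too few to decide it. Of the 114 tested, 18 were called changed, and IFI27 on the interferon list and FDFT1 on the cholesterol list are among the 96 that were not.

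All 35 splits of the 8 libraries into 4 and 4 were fitted. For genes changed, 1 split, the real one, gave as many as 7794, and the highest other gave 2. For genes higher the real 3878 stood against 1 at most, for genes lower 3916 against 1, and for changes of at least 2-fold 1238 against 2, again with 1 split as large. The real split ranked highest of the 35, the best rank this design allows. Every other split mixes the groups, which raises the spread within its groups, so its counts cannot show what chance alone would give. For lists called by camera the real split gave 15 and was the only 1 as large, but the highest other gave 14 with 0 genes changed. Several more splits with 0 genes changed gave 12 or 13 lists. Every split with 6 to 14 lists kept all but 1 library of each group together, so part of the real difference stayed in it. Splits that mixed the groups evenly gave 0 to 5 lists. The number of lists called at the preset correlation thus followed how much of the real difference a split kept. The high counts of the uneven splits do not show what chance gives.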

How the results depend on the processing

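No named gene turned its direction past the threshold. Of 2030 pairs of a named gene and an alternative, 1998 kept their call and direction, and 32 pairs, in 7 genes, among them BNC1, PMVK, RET, TLR3, TUBB3 and UCHL1, lost the call, with adjusted p up to 0.222. Leaving out each library in turn gave 7152 to 7938 genes changed, 3518 to 3951 higher, 3542 to 3987 lower, 1280 to 1326 changed at least 2-fold, 13 to 16 lists, and a CDH11 log2 fold change of -5.11 to -5.04. The fewest genes changed were without knockdown replicate 2 and the most without knockdown replicate 3. Over the other alternatives genes changed ranged from 7484 to 8167 and the CDH11 value from -5.09 to -5.02. The count of changes of at least 2-fold depended on the filter. It was 889 with the filter at a CPM of 1, 1478 in DESeq2 and 1727 with no filter on low counts, against 1238 in the main test. Library size alone moved the median of all genes to 0.07 and the split to 4927 higher and 3240 lower, 60.3% higher against 49.8%.

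Camera with an estimated correlation called 0 lists against 15. For those 15 the estimate ran from 0.0126 to 0.475, against the preset 0.01, and the test then also has only the residual degrees of freedom of the 8 libraries. Fry called 24, which tests another hypothesis. With glmTreat against a fold of 1.2, 3556 genes passed where 1238 passed the limit on the fitted fold of 2, with 1182 shared; the form of the test and its threshold both differ. The replicate number as a block gave 7683 genes changed and 15 lists. The numbers do not pair the libraries: the correlations of same-numbered libraries were 0.01, -0.01, 0.01 and 0.09, and only number 4 was best matched to its own number both ways. DESeq2 gave 10666 of its genes no adjusted p.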

Other observations

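The groups of genes in this part were formed from shared gene symbols after the data were seen, 210 families with at least 8 tested members. Of 79 ribosomal protein genes 64 fell and 1 rose, RPS10, with a median log2 fold change of -0.30, between -0.31 and -0.23 over the 4 scalings tried. The camera adjusted p was 1.64e-09, and the adjusted p = 0.737 with an estimated correlation, and pseudogene copies make these reads uncertain. Among the families that passed upward were the UTP family of the small-subunit processome (9 of 10, median 0.31), the RNA exosome (EXOSC, 8 of 10, 0.37), the RRP genes of ribosomal RNA processing (6 of 8, 0.33), the DDX helicases (20 of 33, 0.25) and the nucleoporins (NUP, 14 of 21, 0.24). Their camera adjusted p values were 0.00843, 0.0158, 0.0283, 0.00133 and 0.00843, and the adjusted p = 0.467 with an estimated correlation for each but NUP, at 0.655. The proteasome genes (PSM) passed upward as well (camera adjusted p 0.0380, and an adjusted p = 0.850 with an estimated correlation). Several other families that act on RNA did not pass in camera, with adjusted p of 0.0669 for NOP, 0.419 for NOL, 0.0542 for DHX, 0.676 for RBM, 0.706 for LSM, 0.891 for EIF and 0.955 for SRSF.

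Secreted metalloproteinases of the ADAMTS family fell in 13 of 15 cases and rose in 2, ADAMTS18 and ADAMTS6, with a median of -1.11, a camera adjusted p of 4.10e-04 and an adjusted p = 0.467 with an estimated correlation. The clustered protocadherins fell as well, 19 of 22 in the gamma cluster (median -0.72) and 12 of 15 in the beta cluster (-0.73), with none higher. Their camera adjusted p values were 3.32e-06 and 0.00506, and the adjusted p = 0.467 with an estimated correlation for both. Gamma cluster transcripts share exons, so their reads are uncertain. Septins, which form cytoskeletal filaments, fell in 9 of 10 cases with none higher, with a median of -0.28, a camera adjusted p of 0.0107 and an adjusted p = 0.467 with an estimated correlation.

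In the scan of 16127 7-base words over 3' UTRs, chosen before its result was seen, 1 word passed the permutation threshold for lower fold changes and 2 for higher. The lower word, GACATAT, was in 1150 genes, whose log2 fold change differed by a fitted -0.11 ± 0.0175 (standard error), with a permutation p of 0.005, the smallest that 200 permutations can give. It occurs at 2 places in the longest CDH11 transcript, in coding exon 6 (chromosome 16, 64991845 to 64991851) and in the 3' UTR in exon 14 (64944570 to 64944576), and 31.2% of the words tested occur somewhere in that transcript. A seed match of the CDH11 siRNA may account for this small shift, but the siRNA sequence was not used here, and the matrix genes without the word kept a median of -0.78. The higher words, TATTTAT in 4646 genes and TTATTTA in 4346, resemble AU-rich elements, which mark many unstable cytokine and early-response transcripts, with fitted shifts of 0.07 and 0.06.

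Of the genes left out of the test for low counts, 2 had at least 3 reads in every knockdown library and 0 in the scramble libraries, IFNB1 among them, and 3 had the opposite, including CPLX2 with 52 reads.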
